A study of Mus musculus with 2 samples.

How the data were processed

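Kidney tissue of 2 male B6CASTF1/J mice of 25 days was assayed by DNase-seq, and the labels give each library a biosample and a biological replicate number of its own, which names the replicates here. The labels give both libraries the same donor code but different biosamples and animal numbers, and they were read as separate animals. Both libraries form 1 group, so no condition could be compared, no replicate block applied and no test between animals was run.

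For each library the authors deposited a pair of peak lists, a footprint list and a list of false discovery rates along the genome, all on the mouse assembly mm10 per the labels. Per the file descriptions that came with each library, the peaks were derived from the filtered reads of that library alone and not from pooled samples. The aligner, the peak and footprint callers and their versions are not given in the sources used here. The deposited signal in the peak lists is the height of each peak, whose low values rise in even steps. The steps differ between the libraries by a factor of 1.72, as heights divided by depth would, and 100% of the heights below 1 lay within 0.05 of a whole number of steps. The peak lists give no summit, p-value or q-value, since those columns deposited by the authors hold -1 and 75 throughout. The footprint list deposited by the authors gives the same false discovery rate (q-value) of 0.01 in every row, which was read as a threshold and not as a measurement. The deposited false discovery rates (q-values) per base were listed only below 0.05, over 36.1 Mb in replicate 1 and 50.8 Mb in replicate 2. The mice carry a CAST/EiJ allele of each autosomal site, while mm10 is a C57BL/6J sequence, and whether the alignment allowed for this is not given in the sources used here. Reads that fail to align because of strain variants would lower peaks.

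The file descriptions did not tell the peak lists apart. By a rule fixed before the data were examined, the list with the narrower mean width was the main one (176 and 175 bp against 180 and 177 bp). It was also the longer, and 100% of its peaks held a base with a false discovery rate up to 0.05. The other list, planned as one of broader regions, turned out to be stricter: it had 80441 and 119139 peaks, and 100% of them held a base at up to 0.001. It served as an alternative. Absolute depth is unknown, so intervals on shares are binomial over peaks or windows and cover counting error only.

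Peaks were compared by overlap of at least 1 bp, with chance overlap from circular shifts of the positions within chromosomes. Heights were correlated over pairs of overlapping peaks. Gene models were GENCODE M21 basic, and sequence came from GRCm38.p6, on which mm10 is based. A promoter peak overlapped 500 bp on either side of any TSS of a gene, and its height is the highest such peak. A gene with several TSSs can thus be counted through one far from its 5' end, and a promoter shared with a neighbour counts for both. Among list genes with heights given below, those of Egf, Pdgfra, Dazl, Cela1, Ins2, Hoxa7, Hoxc9 and Hoxd11 were taken at a TSS away from the 5' end in replicate 2. Distal peaks had midpoints more than 1 kb from every TSS. A locus was the gene body and 10 kb on each side, with 0.5 added to its peak count before the log2 of peaks per kb.

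The 23 gene lists, the 22 consensus motifs, the rule for named genes and all tests were chosen before the data were examined, except where a setting is said to be chosen after. List tests used 100000 random lists of protein-coding genes, matched on 10 classes of CpG observed over expected (promoters) or gene length (loci), with a two-sided p and Benjamini-Hochberg adjustment over the 23 lists, and an adjusted p under 0.05 passed. The lists cover kidney cell types, other organs, housekeeping genes, transcription factors and Hox genes, and a few genes, among them Lhx1, Hoxa11 and Hoxb7, stand in 2 lists. The text names up to 4 members of each list with the highest promoter peak and up to 3 without one, the 10 densest loci of at least 5 kb, the 10 highest shared distal peaks and up to 5 list genes with a promoter peak in 1 library only; some lists are shown with fewer of these.

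Motifs were searched on both strands in 150 bp at the midpoint of 92724 and 138071 distal peaks and in windows 1 kb to either side outside peaks. Footprints were widened by 10 bp on each side and compared with windows of the same width in peaks at places without a footprint. Footprints at promoters were included, and each control window came from a random peak of the same chromosome. Ratios of shares have log-normal 95% intervals, with 0.5 added where a motif had no match, and means over the libraries are geometric. Shuffled sequence was made for 20000 distal peaks per library. X was compared with the 19 autosomes without a test beyond its rank.

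The list tests were tested on simulated data with 21938 genes. Of 200 unchanged lists of 20 genes, 2% (promoters) and 3% (loci) passed at 0.05, and of 200 raised lists 98% and 99.5% did. The planted rises were large and the simulated genes independent, while the real lists had 6 to 28 members. These shares therefore do not hold for smaller effects, shorter lists or neighbouring genes that share peaks. Nor do they hold for lists whose matched promoters are nearly all open. A planted overlap of 60% and a planted motif ratio of 4 were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and BLAST+ 2.17.0 were used. Alternatives covered the overlap required, the peak list, the upper 50% of peaks by height, promoter and locus windows, matching, motif backgrounds, the denominator for X and each library left out.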

Results

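DNase-seq maps accessible chromatin by sequencing the ends that the enzyme DNase I cuts in nuclei. Here it was applied to whole kidney tissue of male B6CASTF1/J mice, the F1 hybrids of C57BL/6J and CAST/EiJ, at 25 days of age. The series holds 1 group of 2 biological replicates and no treated or control group, so the comparisons are between the libraries and between genes, regions and sequence motifs within them. Replicate 1 had 125393 accessible sites (peaks) covering 22.1 Mb, and replicate 2 had 177001 peaks covering 31.1 Mb. The read number of each library is unknown. If heights were divided by depth, the steps in which low peak heights rise put replicate 2 at 1.72 times the depth of replicate 1. Values for both libraries are given in the order replicate 1, replicate 2, and with n = 2 no test between animals was possible.

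Accessible sites of the kidney recurred between the animals, and above all the high ones. Of the peaks of replicate 1, 87.6% (exact 95% binomial interval 87.5 to 87.8) overlapped a peak of replicate 2, against 2.35% after shifting the positions. In the lowest height decile 36.9% of the peaks of replicate 1 recurred, and in the highest decile 99.7%. Replicate 2 held 66961 peaks that replicate 1 lacked, with a median height of 0.373 against 1.23 for its shared peaks, so that 62.2% of its peaks recurred in replicate 1. Over the 109888 peaks of replicate 1 with a partner, heights correlated across regions, which are not independent replicates, with Spearman's rho of 0.930 and Pearson's r of 0.945 on the log2 scale. The median log2 ratio of replicate 2 to replicate 1 was 0.18 (SD 0.50 across peaks), and 95.3% of the peaks lay within 2-fold of that median. With the stricter of the deposited peak lists, 94.98% of the peaks of replicate 1 recurred.

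**Figure D1:**
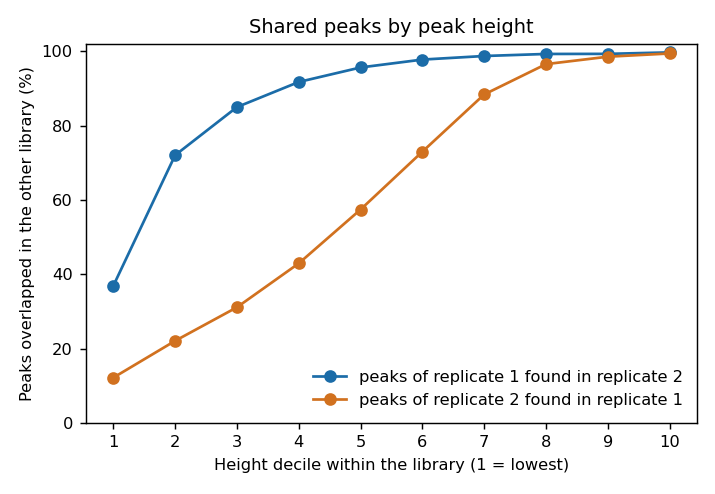
Percent of peaks overlapped by at least 1 bp by a peak of the other library (y axis) against the height decile within the library (x axis, 1 is the lowest); each point is 1 decile of 1 library. In replicate 1 the share goes from 36.9% to 99.7%, and in replicate 2 from 12.2% to 99.4%.

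Footprints, short stretches inside accessible sites that are cut less than their surroundings and can mark bound proteins, numbered 237471 and 493495. Their median widths were 10 and 12 bp, and 91.3% and 87.2% of them lay in peaks of the same library. A footprint was present in 73.3% and 86.7% of the peaks. Of the footprints of replicate 1, 77.2% (95% interval 77.0 to 77.4) overlapped one of replicate 2, against 0.523% after shifts, while 33.4% of those of replicate 2 overlapped one of replicate 1. Replicate 2 had 2.08 times as many footprints and 1.41 times as many peaks. Requiring 50% reciprocal overlap lowered the shared footprints of replicate 1 to 42.6%.

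Promoters were the most enriched class of region. Midpoints within 1 kb of an annotated transcription start site (TSS) made up 24.0% ± 2.87 (SD, n = 2) of the peaks, against 4.37% of random positions outside assembly gaps. Introns held 39.2% and 42.5% of the peaks, close to their 40.1% of random positions, and exons held 4.74% and 5.00% against 2.89%. Intergenic sequence held 30.05% and 30.54% against 52.6%. Promoter peaks were also the highest, with median heights of 1.87 and 1.34, while intergenic peaks had 0.684 and 0.566. Of 21938 protein-coding genes, 14329 (65.3%) had a peak within 500 bp of a TSS in both libraries. The share varied with the CpG content of the promoter: in the lowest decile of CpG observed over expected 6.43% of the genes had such a peak, and in the highest decile 97.7%.

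The genes that mark proximal tubule cells, the most numerous cells of the kidney cortex, had open promoters in 26 of 28 cases, where random gene lists matched on CpG content gave a mean of 9.66. Pck1, which makes the rate-limiting enzyme of gluconeogenesis (chromosome 2, 173153048 to 173159273), had promoter peaks of height 6.03 and 5.44. Lrp2, the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), had 6.93 and 4.53. The water channel gene Aqp1 had 5.05 and 4.53, and the cytochrome P450 gene Cyp4b1 had 3.85 and 5.45. Slc22a8, an organic anion transporter gene on chromosome 19, had no promoter peak in either library, although 13 and 14 peaks lay within its body and 10 kb on each side. The list stood above random lists by a two-sided permutation test with Benjamini-Hochberg adjustment over 23 lists (adjusted p = 0.000153, from an unadjusted permutation p of 2e-05, the smallest that 100000 random lists can give). Genes are not replicates, so this p and those below describe these libraries.

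Promoters of other segments and cell types of the kidney were open as well, though only some of these lists passed the test against random lists. Loop of Henle genes had promoter peaks in both libraries in 11 of 13 cases against 6.51 at random (permutation adjusted p = 0.0113). Among them Egf, the epidermal growth factor gene, had heights of 9.95 and 11.5 and the chloride channel subunit gene Bsnd 2.11 and 2.68, while the tight junction gene Cldn19 had none. The Egf peak of replicate 2 lay inside the gene, at 129725041 to 129725220 on chromosome 3, while the 5' end of Egf is at 129755316. All 15 endothelial genes had such peaks against 9.50 at random (permutation adjusted p = 0.000644), led by Ehd3 (8.14 and 7.13), Esam (5.81 and 6.12), Eng (5.34 and 5.53) and Kdr (4.59 and 5.44). Stromal and smooth muscle genes had 11 of 14 against 5.95 (permutation adjusted p = 0.0120). There the growth factor receptor gene Pdgfra had 6.46 and 5.12 and the smooth muscle myosin gene Myh11 3.27 and 2.87, while Ren1, which encodes renin, Postn and Cnn1 had no promoter peak. When only the 5' end of each gene counted as its TSS, a setting chosen after seeing the data, the loop of Henle (permutation adjusted p = 0.232), endothelial (0.546) and stromal lists (0.194) no longer passed. Random lists were matched on the highest CpG value over all TSSs of a gene, in this setting too. They were not matched on the number of TSSs, which gives genes with many of them more chances of a peak. The loop of Henle and stromal lists also missed the threshold with the stricter peak list (0.112 and 0.215), with unmatched random lists (0.296 and 0.494) and with the upper 50% of peaks by height (0.0622 and 0.732), and the stromal list without replicate 1 (0.0511).

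The remaining kidney lists did not pass the test. Distal convoluted tubule genes had 9 of 10 promoters open against 6.99 at random, with Cnnm2, a magnesium transport gene, at 24.1 and 30.7 and the kinase gene Wnk4 at 6.999 and 8.003. Collecting duct principal cells had 10 of 12 against 7.23, including the transcription factor gene Tfcp2l1 (10.4 and 6.38) and Scnn1g, a subunit of the epithelial sodium channel (6.07 and 5.45). With replicate 1 alone this list passed (permutation adjusted p = 0.0274). Podocyte genes had 12 of 13 against 10.2, with Cd2ap at 20.9 and 18.0 and Podxl at 5.19 and 4.39. Intercalated cells had 7 of 13 against 4.88. The ammonia transporter gene Rhbg had 3.91 and 4.25 there, and Atp6v1g3, Slc4a1 and Slc4a9 had no promoter peak. Nephron progenitor genes, such as Sall1 (7.94 and 4.22) and Lhx1 (4.85 and 4.33), were open in 10 of 12 cases against 10.6. The immune list had 2 of 14 against 3.33, Cd74 (1.14 and 1.30) and Lyz2 (0.461 and 0.248), and the erythroid list had 1 of 12, Tal1 (2.41 and 1.699). No promoter peak was found at Ptprc, Cd79a or the globin genes Hba-a1, Hba-a2 and Hbb-bs, and the near-identical copies of the globin genes make this uncertain. With random lists not matched on CpG content the immune (permutation adjusted p = 0.00146) and erythroid lists (0.000828) lay below random, and the nephron progenitor list did in the upper 50% of peaks (0.0400).

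Genes of other organs were open less often than CpG content gives in several lists. Neuronal genes had promoter peaks in both libraries in 8 of 17 cases against 13.2 at random (permutation adjusted p = 0.00353), and heart and skeletal muscle genes in 2 of 18 against 5.94 (0.0317). Male germ cell genes had 2 of 11 against 7.11 (permutation adjusted p = 0.000230), and adrenal cortex genes 0 of 9 against 2.37 (0.0257). Stmn2, Gad1 and Grin2b of neurons, Myh6, Myh7 and Tnnt2 of muscle, Ddx4, Stra8 and Prm1 of germ cells, and the steroid synthesis genes Cyp11b1, Cyp11b2 and Cyp21a1 had no promoter peak in either library. Exceptions were Mylpf, a muscle myosin light chain gene (14.0 and 9.77), Ryr2 (4.26 and 2.36), Dazl (8.26 and 6.07) and Syn1 (2.82 and 2.31). The Dazl peak of replicate 2 lay inside the gene, at 50292721 to 50292920 on chromosome 17, while the 5' end of Dazl is at 50293636. Hepatocyte genes had 3 of 18, Apob, Fga and Trf, against 4.62, and pancreas genes 2 of 12 against 4.86, Cela1 (3.09 and 2.92) and Ins2 (0.410 and 0.298), neither past the threshold. The Cela1 and Ins2 peaks of replicate 2 lay inside the gene models, away from the 5' ends. The pancreas list did pass below random with promoters widened to 2 kb (permutation adjusted p = 0.0345), unmatched random lists (0.00497), the stricter list (0.0408) and 5' ends (0.00345), and the hepatocyte list with unmatched random lists (0.000767). In replicate 2 alone, where 13 of the 17 neuronal genes had a promoter peak, the neuronal list lost its call (permutation adjusted p = 0.980). So did the muscle (0.0739) and adrenal lists (0.399) there, and the adrenal list in replicate 1 alone (0.450). The neuronal and muscle calls also ended with promoters of 2 kb (0.439 for both), where the adrenal list had 3 of 9 against 2.97 (permutation adjusted p = 1). Further losses were the neuronal call with unmatched random lists (0.260), and the muscle and adrenal calls in the upper 50% of peaks (0.179 and 0.0957), with the stricter list (0.0994 and 0.0601) and at the 5' ends (0.382 and 0.715).

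Kidney transcription factors had open promoters in 21 of 22 cases against 18.7 at random, which did not pass. The nuclear receptor genes Esrra (26.5 and 35.6) and Ppara (16.9 and 13.5) and the nephron lineage gene Pax8 (8.27 and 6.89) were the highest besides Hoxb7, and Tfap2b was the one member without a peak. Transcription factors of other lineages had 3 of 20, Sox2 (2.09 and 2.04), Foxa3 (1.701 and 1.03) and Neurog2 (0.624 and 0.705), against 15.9 at random (permutation adjusted p = 0.000153). In replicate 2 alone, 6 of the 20 had a promoter peak. Myod1, Myf5 and Sox10 had none. All 16 housekeeping genes were open against 15.0 at random, with Eef2 at 28.1 and 26.5 and Rplp0 at 25.0 and 27.1. This list and the kidney transcription factors passed above random only with unmatched random lists (permutation adjusted p = 0.00497 for each).

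Hox promoters were mostly open except in the last paralog groups. Those of groups 1 to 8 had 20 of 23 promoters open against 19.6 at random and those of groups 9 to 11 had 7 of 10 against 9.27, neither past the test, while groups 12 and 13 had 1 of 6 against 5.21 (permutation adjusted p = 0.000153). Hoxa7 (12.2 and 10.7), Hoxa4 (13.6 and 9.14), Hoxa10 (12.2 and 12.6) and Hoxc10 (11.7 and 18.3) had high promoter peaks. Hoxc13 (1.53 and 2.13) was the open gene of the last groups, and Hoxa13, Hoxb13 and Hoxd12 had none. Several Hox promoters had a peak in replicate 2 only: Hoxc8 (1.76), Hoxc9 (0.954) and Hoxd11 (0.825). The peaks of Hoxc9 and Hoxd11 lay at a TSS away from the 5' end. Meox1 had one in replicate 1 only (1.33). In replicate 2 alone, 3 of the 6 genes of groups 12 and 13 had a promoter peak. The call on these groups missed the threshold there (permutation adjusted p = 0.0511) and with unmatched random lists (0.0730).

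**Figure D2:**
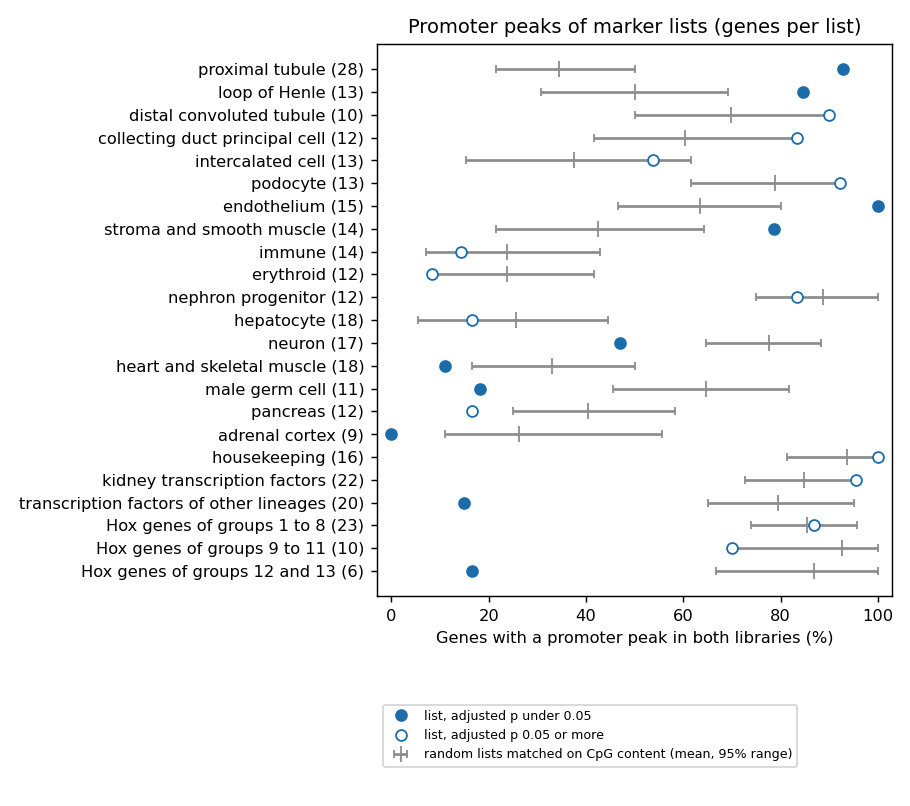
Percent of each list's genes with a promoter peak in both libraries (x axis) for the 23 lists (y axis, number of genes in brackets); filled circles passed the adjusted permutation test, open circles did not, and grey bars give the mean and 95% range of random lists matched on CpG content. Proximal tubule genes lie at 92.9% and adrenal cortex genes at 0%.

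Peak density over whole loci, that is the gene body and 10 kb on each side, set apart partly different lists. Hox genes of groups 1 to 8 had 4.43 times and those of groups 9 to 11 had 4.29 times the median density of random lists matched on gene length (permutation adjusted p = 0.000153 for each). Kidney transcription factors had 2.88 times (0.000153), housekeeping genes 1.95 times (permutation adjusted p = 0.0224) and proximal tubule genes 1.698 times (0.0110). Endothelial genes, at 1.68 times, did not pass (permutation adjusted p = 0.0749). They did where peaks near a TSS (0.00276), replicate 2 (0.0389) or, as a setting chosen after seeing the data, unshared peaks (0.0270) were left out, and nephron progenitor genes, at 1.62 times, passed in replicate 1 alone (0.0448). In the main setting no list was below random at an adjusted p under 0.05, nor at an unadjusted p under 0.05, with the lowest ratios in pancreas (0.524), male germ cell (0.578), hepatocyte (0.635), erythroid (0.683) and neuron (0.691). The loop of Henle had 1.22 times, principal cells 1.32, groups 12 and 13 of the Hox genes 1.34, immune genes 1.11 and stroma 1.10, and the other lists lay between 0.926 and 1.05. With 50 kb on each side kidney transcription factors had 1.79 times, nephron progenitor genes 0.869, hepatocyte 0.976, male germ cell 0.942 and Hox groups 12 and 13 2.5005 times (permutation adjusted p = 0.0780). In the upper 50% of peaks Hox groups 1 to 8 had 7.16 times, the loop of Henle 1.87, podocytes 0.622, neurons 0.455 (unadjusted permutation p = 0.0317, adjusted 0.121), pancreas 0.331 and adrenal cortex 0.232. Without peaks near a TSS the loop of Henle had 1.86 times, intercalated cells 1.64, adrenal cortex 1.44, pancreas 1.0496 and male germ cell 0.946, none past the adjusted test. Neighbouring Hox genes share peaks, so the p-values of the Hox lists are likely too small, by an amount that was not measured. Hoxb7 is in both a Hox and the kidney list, so those lists are not independent. The housekeeping call ended when peaks within 1 kb of a TSS were left out (permutation adjusted p = 0.615).

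Of all protein-coding genes of at least 5 kb, the densest loci were those of Hoxa9 (1.20 peaks per kb, 28 and 39 peaks), Hoxa7 (1.15), Zfp503 (1.01), Midn (0.997), Hoxb9 (0.955), Hoxb6 (0.894), Hoxa10 (0.894), Hoxa3 (0.848), the T-box factor gene Tbx2 (0.833) and Atp5d (0.809). Within the lists, the kidney factor gene Pax8 had 16 and 30 locus peaks, Klhl3 of the distal convoluted tubule had 20 and 30, and Scnn1a of the collecting duct had 14 and 20. The loci of Ins1 and Iapp in the pancreas list and of Hbb-bs in the erythroid list held no peak in either library.

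Distal peaks, those more than 1 kb from every TSS of the basic annotation, included some of great height. The highest shared one was at chromosome X, 169998261 to 169998420, in an intron of Mid1, with heights of 62.4 and 87.7, and another Mid1 intron peak at 169997881 to 169998080 had 31.7 and 36.2. The next lay in an exon of Lars2 (chromosome 9, 123461921 to 123462080, heights 46.1 and 41.9) and 35.5 kb from Pak3 on chromosome X (143482981 to 143483140, heights 35.0 and 51.5). A peak 17.9 kb from Tfap4 on chromosome 16 (4541821 to 4542080) had 28.8 and 55.6 and lay 135 bp from a TSS of the comprehensive annotation. Further ones were 72.7 kb from Irf2bp2 (28.1 and 39.1), 21.6 kb from Igf2bp3 (32.4 and 34.1), in an intron on chromosome 2 at 30658501 to 30658720 (29.1 and 35.9), in an exon of Cers5 (27.8 and 35.6) and 4.79 kb from Map1lc3b (27.1 and 34.5). Of these 10 peaks, 50% had a near-identical second place in the assembly: those in Mid1 and Lars2 and near Pak3 and Igf2bp3.

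Distal peaks carried binding sequences of factors that act in kidney epithelium and of general chromatin proteins. The HNF4 consensus CAAAGTCCA occurred in 0.932% of distal peaks against 0.188% of flanking windows 1 kb away, a ratio of 4.96 (4.83 and 5.10 in the libraries), and the HNF1 consensus GTTAATNATTAA reached a ratio of 6.01 (5.76 and 6.27). HNF1 and HNF4 are families of transcription factors of kidney tubule, liver and gut. The consensus of the insulator protein CTCF, CCASYAGRKGGC, was found in 5.504% of distal peaks against 0.0443% of flanks, a ratio of 123. That of the neuronal repressor REST, TTCAGCACCNNGGACAG, was found in 0.107% against 0.000482%. The REST ratio of 225 rests on 1 background match per library (lowest bound of the 95% counting intervals 29.0). NF1, with TTGGCNNNNNGCCAA, had 56.1. Ratios were also above 1, with 95% intervals above 1 in both libraries, for NRF1 (4.64), CEBP (4.55), SP/KLF (3.71), GRHL (3.10), MYOD (2.93), ETS (2.49), SPI1 (2.36), TFAP2 (2.16), the glucocorticoid receptor (1.90), TEAD (1.704) and AP-1 (1.61). GATA (0.677) and OCT (0.795) lay below 1, and RUNX (0.983) differed from 1 in neither library. ESRR (1.15), MEF2 (1.14) and FOX (1.05) were above 1 by their intervals in replicate 2 only (1.29, 1.16 and 1.07).

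Some of these ratios changed with another background. Distal peaks had 52.6% and 52.0% GC against 45.1% and 45.0% in the flanks. Against dinucleotide-shuffled sequence of the same peaks the ratios of TFAP2 (0.879) and CEBP (0.630) fell below 1 and that of GATA (1.04) lay above it, none by its intervals in both libraries, and GRHL (1.97) passed in replicate 2 only (1.55 in replicate 1). OCT (1.57), ESRR (2.38), MEF2 (3.93), FOX (2.04) and RUNX (1.45) were above 1 in both libraries there. CTCF (46.4), NF1 (9.50, with 6.33 and 14.3 in the libraries) and MYOD (1.75) had smaller ratios than against flanks, and SP/KLF (8.69) and SPI1 (3.97) had larger ones. Those of REST (52.9), NRF1 (30.05) and HNF1 (14.2) rest on at most 2 matches per library in shuffled sequence. In the upper 50% of peaks OCT (0.879) was below 1 in replicate 2 only, and CTCF had a ratio of 195. A consensus is shared by the members of a factor family, so a match names no single protein.

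Compared with windows in peaks that hold no footprint, footprints were richest in REST, NRF1 and CTCF sequences. NRF1, an activator of housekeeping and mitochondrial genes with the consensus GCGCATGCGC, had a ratio of 39.98 (37.3 and 42.8), REST 64.4 (128 and 32.4 in the libraries, on 1 and 5 background matches, lowest bound 13.3) and CTCF 17.2 (16.3 and 18.2). NF1 (7.74), SP/KLF (6.78), CEBP (3.45), TFAP2 (1.61), HNF4 (1.48) and ETS (1.28) were also above 1 in both libraries by their 95% counting intervals. HNF1 (1.71) and GRHL (1.26) were so in replicate 2 only. Ratios below 1 were found for FOX (0.5498), GATA (0.564), SPI1 (0.698), RUNX (0.720), the glucocorticoid receptor (0.724), OCT (0.768), TEAD (0.774), AP-1 (0.802) and MYOD (0.837), while ESRR (0.773) was below 1 in replicate 1 only (0.575) and MEF2 (0.783) in replicate 2 only (0.707). Footprint windows had 59.5% and 56.7% GC against 54.2% and 53.1% in the control windows. Footprints at promoters were included, and control windows came from random peaks of the same chromosome, so distance from a TSS was not matched. NRF1 matched 448 and 471 footprints but 82 and 94 distal peaks, and SP/KLF 5702 and 7879 against 1467 and 2070. How much of these ratios reflects promoters was not tested. Against windows 50 bp away the order was another: NF1 (3.36), REST (2.99, with 4.41 and 2.03 in the libraries), HNF1 (2.53), CTCF (2.26, with 3.29 and 1.56) and HNF4 (2.11) had the highest ratios, while NRF1 had 1.61 and SP/KLF 1.60. Unlike the control windows, these shifted windows were not kept free of footprints, which could pull the ratios towards 1. HNF1 was above 1 in both libraries there, and the calls on CEBP (1.36), OCT (0.879) and the glucocorticoid receptor (0.876) ended. AP-1 (1.07), TEAD (1.05), SPI1 (1.07) and MYOD (1.13) lay above 1, though not by their intervals in both libraries. ESRR had 0.787 in replicate 1 and 1.36 in replicate 2, above 1 by its interval in replicate 2 only.

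**Figure D3:**
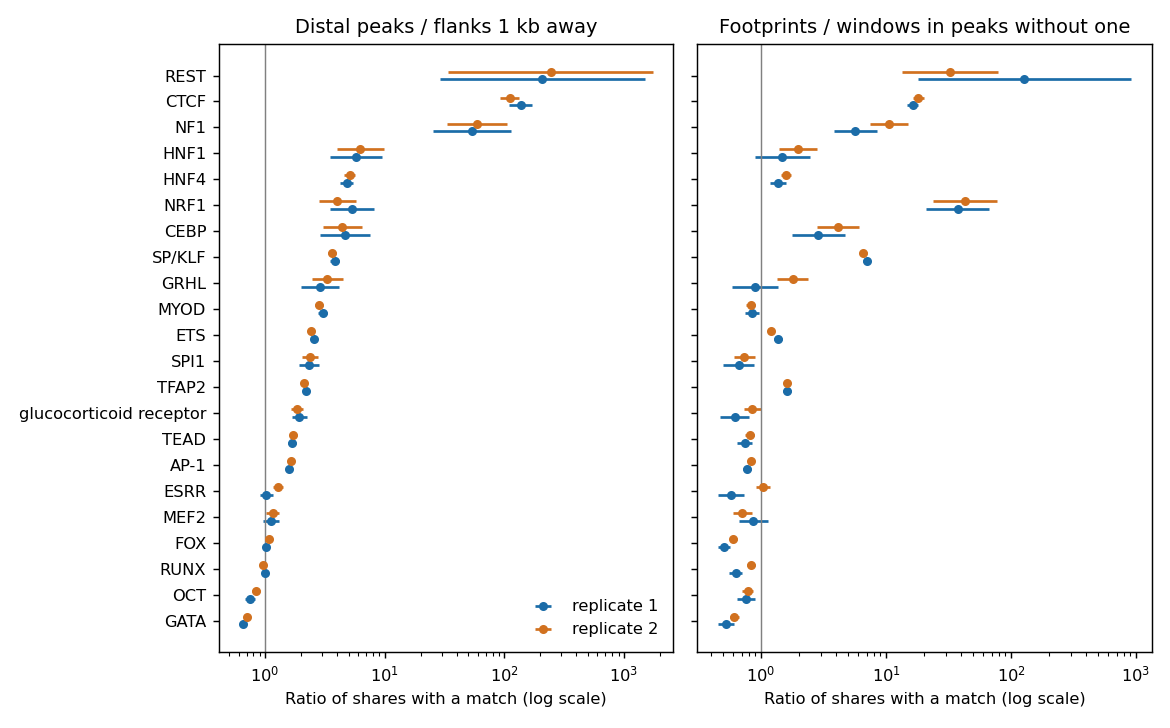
Ratio of the share of windows with a consensus match to the background share (x axis, log scale) for 22 motifs (y axis). The left panel shows distal peaks and the right panel all footprints, those at promoters included. Points are libraries and bars their 95% counting intervals. At distal peaks CTCF has a ratio of 137 in replicate 1 and 111 in replicate 2, and GATA lies below 1 in both.

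The X chromosome, present once in these males, had fewer and lower peaks than every autosome. It held 20.1 and 27.7 peaks per Mb, against autosomal medians of 52.8 and 74.6 and lowest autosomes at 39.9 and 55.3. The ratio of X to the autosomal median was 0.376 ± 0.00645 (SD, n = 2). The median height of X peaks was 0.470 and 0.378 against 0.889 and 0.691, a ratio of 0.538 ± 0.0127 (SD, n = 2). Counted per protein-coding gene, X had 3.47 and 4.78 peaks against 6.21 and 8.72. In the upper 50% of all peaks by height the X peaks that remained were as high as autosomal ones, with a ratio of 1.03.

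**Figure D4:**
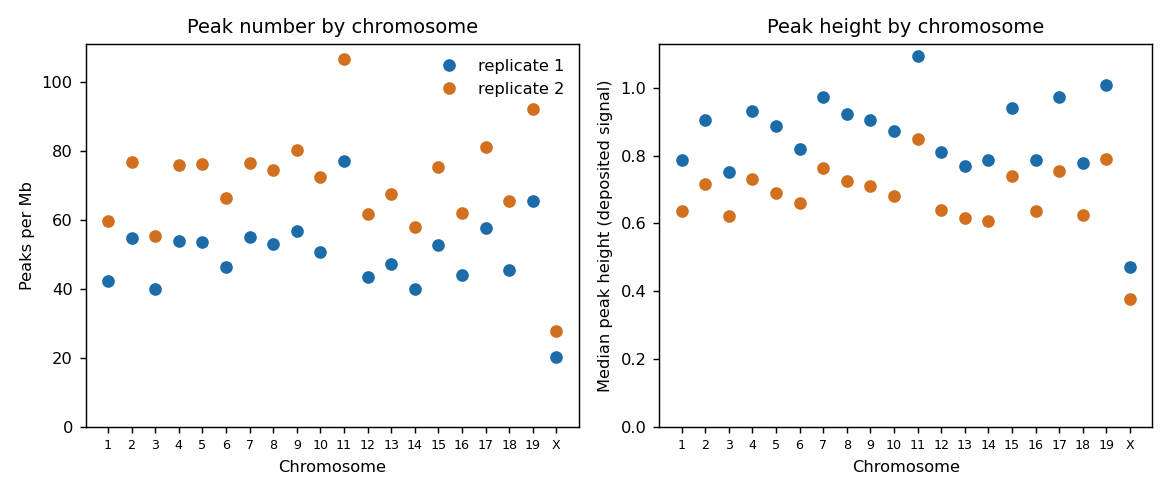
Peaks per Mb (left) and median peak height in the deposited signal (right) for the autosomes and X (x axis, Y is not drawn); points are the libraries. X lies below every autosome in both panels, at 20.1 and 27.7 peaks per Mb.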

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

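The settings with only the 5' end of each gene, replicate 2 reduced to the peak number of replicate 1, and locus peaks found in both libraries were chosen after seeing the data. Over 104 values, 513 alternatives were run, of which 425 counted as unchanged. A list or motif that passed in the main setting had to keep its direction and call. One that had not passed only had to stay so, whatever its direction. Counts of calls had to stay within a fixed factor, and other values within their spread or counting interval. The proximal tubule list passed at promoters and loci in every setting run. Shared peaks of replicate 1 went to 78.2% with 50% reciprocal overlap, 88.2% for equal numbers of the highest peaks, 94.98% with the stricter list, 79.0% with replicate 2 reduced, and the reverse share was 62.2%. The rank correlation of heights was 0.898 for the highest peaks and 0.933 with reciprocal overlap. Shared footprints went to 42.6% with reciprocal overlap and 33.4% in reverse. The promoter share was 32.6% within 2.5 kb and 33.2% in the upper 50% of peaks. Lists above random at promoters fell from 4 to 2 in the upper 50% of peaks, to 2 with the stricter list and to 1 at 5' ends, and ranged from 3 to 5 with a library left out. Lists below random, 6 in the main setting, ranged from 2 to 5 with a library left out and were 8 with unmatched random lists, 4 with promoters of 2 kb and 5 each in the upper 50%, with the stricter list and at 5' ends. The adrenal cortex list lay 0.0267 genes above random with promoters of 2 kb. Motifs below 1 at peaks numbered 1 in the upper 50% and 0 against shuffled sequence, where TFAP2 (0.879), CEBP (0.630), GATA (1.04) and OCT (1.57) reversed, ESRR, MEF2, FOX and RUNX came above 1 in both libraries and GRHL lost its call. Motifs below 1 at footprints numbered 3 against windows 50 bp away, where AP-1 (1.07), TEAD (1.05), SPI1 (1.07) and MYOD (1.13) reversed, HNF1 gained a call and CEBP, OCT and the glucocorticoid receptor lost theirs. The X ratio of peaks per Mb was 0.230 in the upper 50% and 0.553 per gene, and that of heights 1.03 in the upper 50%, which keeps only high peaks by construction. The cause of the other shifts was not tested.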

Other observations

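Gene families differed in openness. Each was chosen by symbol after the main results were seen and tested as the lists were, with adjustment over 50 tests. Some members also stand in the lists, among them Irx1, Irx2 and Irx3 of the kidney transcription factors and solute carrier genes of the proximal tubule. Results of such families partly repeat the earlier calls. Of 356 solute carrier genes, the membrane transporters of which tubules express many, 276 had a promoter peak in both libraries against 246 at random (permutation adjusted p = 9.09e-05), and their loci held a median of 7.5 peaks against 6. Slc38a10, Slc30a1 and Slc22a5 had the highest promoter peaks. Glutathione transferases had 19 of 22 against 11.8 (permutation adjusted p = 0.000769), the vacuolar proton pump 21 of 23 against 17.1 (0.0192), glucuronosyltransferases 9 of 22 against 4.35 (0.0392) and cytochromes P450 37 of 100 against 25.2 (0.00314). The P450 loci nevertheless held a median of 2.25 peaks against 5. Iroquois factor loci, with Irx5, Irx3 and Irx2 in front, held a median of 10.2 peaks against 3.5 (permutation adjusted p = 0.00780). Of 1135 olfactory receptor genes 14 were open against 156, of 329 vomeronasal receptor genes 1 was, Vmn1r4, against 30.6, and of 53 keratin genes 8 against 22.7. Forkhead factors (24 of 44 against 36.8) and protocadherins (35 of 69 against 50.4) were also below random, all at a permutation adjusted p = 9.09e-05, where the unadjusted p is 2e-05, the smallest that the random lists can give. Zinc finger genes had more open promoters than random (343 of 394 against 305) and fewer locus peaks (3.5 against 5). In all, promoters of 6 of the 25 families passed above random and 5 below, and loci of 4 above and 6 below. The symbol patterns were narrowed after a first run that had taken in unrelated genes, and with that the proton pump came to pass at promoters while the sodium-coupled sugar transporters (9 of 13 against 6.25, permutation adjusted p = 0.122) no longer did. Clustered members share peaks, and whether reads that align to several places were kept is not given in the sources used here.

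The 100 kb window with the most shared peaks, 43 against a mean of 4.03, lay in Tns1 on chromosome 1 (74000001 to 74100000). The next held Midn and Stk11 on chromosome 10 (41 peaks), Nr1d1 and Thra on chromosome 11 (40), Bahcc1 (39), and with 38 each Irf2bpl, a part of the Hoxa cluster and Jund. On the Y chromosome promoter peaks lay at Kdm5d (1.52 and 2.66), Eif2s3y (2.25 and 3.52), Uty (2.29 and 3.88) and Ddx3y (2.26 and 3.39), and the Xist promoter had none. The noncoding genes Malat1 (16.9 and 12.1) and Neat1 (14.2 and 14.5) had high promoter peaks, and H19 had none.

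Of the tests that follow, that of depth and that of the 10 highest distal peaks were chosen after the result was seen. A first pattern was the low number and height of X peaks. More repeats on X were argued against as the whole cause of the low number. Per Mb of sequence not masked as repeat, X still had 0.477 times the autosomal median, with 37.8 and 52.1 peaks against lowest autosomes at 61.1 and 86.1. Over all sequence outside assembly gaps the ratio was 0.376, so masked repeats may account for a part. A candidate explanation is the single X of males against 2 copies of each autosome. At distal peaks with a CTCF match, X heights were 0.446 times those of autosomes (0.423, 95% bootstrap interval 0.357 to 0.497, and 0.469, 0.381 to 0.557), and at promoters matched on CpG content 0.578 and 0.606 times, each ratio within the range of 0.4 to 0.65 set in advance, though the intervals of those at promoters reach 0.661 and 0.697. The deficit in number was milder at promoters, where 457 and 480 X genes had a peak against 539 and 562 expected from CpG content (0.848 and 0.854 times), than in peaks per Mb. These measures are unlike, since at promoters a gene counts once whatever its number of peaks. All peaks per protein-coding gene stood on X at 0.558 and 0.549 times the autosomal median. How far a lower height accounts for the smaller number of X peaks was not tested, and as no females were measured the single X remains a hypothesis.

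A second pattern was the set of 100 highest distal peaks. Near-identical places that the assembly holds were found for 10% of them (95% Wilson interval 5.52 to 17.4) against 4.67% of 300 other shared distal peaks, so they do not account for the set, while among the 10 highest they were found for 50%, which leaves the explanation open there. For the Mid1 peaks, which had 4 and 5 other places, this may reflect the pseudoautosomal region, whose boundary lies in Mid1 in C57BL/6. Which sequences held the other places was not examined, and patch or alternate sequences of the same place were not set apart from true copies. Promoters that the basic annotation leaves out were within 1 kb for 16% (10.1 to 24.4) against 5.33% of the others, too few to explain the set. Copies absent from the assembly were not tested, the explanation having been narrowed to those it holds after the result was seen, and the design names no biological explanation.

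The last pattern was the larger number of peaks in replicate 2. Sequencing depth stays open: of its 66961 unshared peaks, 3.53% had a height that, scaled to replicate 1, was above the median of that library, but peaks near the calling threshold are the ones that go unshared whatever the reason, so this share does not decide. Another cell makeup of the second kidney was looked for at promoters of 8 kidney cell type lists with at least 5 genes. The largest distance of a list from random lists was 0.19 in the log2 height ratio, for intercalated cells, and no list of 14 passed even unadjusted. The random lists spread wider than that, so a small shift in cell makeup cannot be excluded.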
